A study of Mus musculus with 8 samples.

How the data were processed

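Total RNA of RAW264.7 cells, a mouse macrophage-like cell line, was hybridized to 8 one-colour (Cy3) Agilent whole mouse genome arrays, design 014868 per the file headers. There were 4 treatments, each with 1 array at 12 h and 1 array at 24 h: untreated control, all-trans retinoic acid (ATRA), interleukin-13 (IL-13), and IL-13 together with ATRA. The labels number the 12 h array of each treatment as replicate 1 and the 24 h array as replicate 2, and they give no doses. The labels do not say that the 8 cultures were separate, so p-values measure only the spread between these arrays.

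Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.1.1, which subtracted background and removed spatial trends within each array. The values used here were its processed signals in the unit intensity, deposited with no normalization between arrays. Feature Extraction also gave other 0 or 1 flags per spot, per the file headers, of which those for well above background, saturation, non-uniform spots and outlying spots were read. The authors also deposited a table of values on a log2 scale, with 1 column per array. Its columns had the same minimum of 0.752 and the same maximum of 18.2, which is the form that quantile normalization gives. Each column had a Spearman correlation of at least 0.999996 across probes with the processed signals of its own array and of at most 0.963 with those of any other array. The method behind that table was not stated in the sources used, and the table served only as an alternative.

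The 75th percentile of the signal ranged from 448 on the IL-13 array at 12 h to 739 on the IL-13 array at 24 h. The percentage of probes well above background ranged from 54.1% to 61.4% over the 8 arrays. By the mean flag of their spots, 0 probes counted as saturated on any array. The number of arrays, 2 per treatment, limits the precision. All 12 h arrays lay on slide 1 and all 24 h arrays on slide 2, so time and slide cannot be told apart, while every treatment comparison was made within each slide.

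Control spots were removed, which left 43379 spots of 41174 probes. Spots that Feature Extraction called non-uniform or outlying were set to missing. The signals of repeated spots were averaged before the log2 was taken, which left 49 probes with a missing value. From each array the log2 of its 75th percentile was subtracted and the mean of the percentiles over the 8 arrays was added. Probes well above background on both arrays of at least 1 treatment were kept (24017 probes). Gene names were taken through RefSeq accessions for 27668 probes, through symbols for 5589 probes and through synonyms for 471 probes, and 7446 probes kept the name in the deposited annotation. For each gene the probe with the highest mean signal was used, which gave 15440 genes. No genome build was provided, so no positions are given.

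Differences were fitted with limma 3.58.1 in R 4.3.3 with a term for each of the 4 treatments and a term for time, which left 3 residual degrees of freedom. The residual spread of this fit is therefore how far the treatment differences disagreed between 12 h and 24 h. Empirical Bayes moderation gave a prior of 2.41 degrees of freedom and a prior standard deviation of 0.15 on the log2 scale. A gene counted as called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all 15440 genes. The comparisons were IL-13 against control, ATRA against control, IL-13 with ATRA against IL-13, IL-13 with ATRA against ATRA, their interaction, and 24 h against 12 h. A model with all pairwise interactions, which left 1 residual degree of freedom, tested whether the effect of IL-13 or of ATRA differed between times. Genes that differed at least 2-fold the same way at both times were counted without a test. Errors given with ± are limma's standard errors on the log2 scale, and values for 12 h and 24 h are differences between 2 arrays.

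Where 1 of the compared treatments was well above background on 0 of its 2 arrays, the fitted value is no bound. Its fold is then given as at least N-fold, computed from the mean log2 signal of the brighter treatment and a limit for the dimmer one. For this limit, each array gave the higher of the gene's own log2 signal and that array's lowest log2 signal well above background. These were averaged over the 2 arrays. Where a treatment was well above background on 1 of its 2 arrays the fitted value is given, which rests in part on a signal near background. For Mlxipl and Col14a1 another probe was well above background on an array of the dimmer group, and no bound is given for them between IL-13 with ATRA and IL-13.

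Before the data were examined, 27 gene lists (450 genes) were fixed, together with the comparisons, the tests, the alternatives and the rule for naming genes. For each of the first 3 comparisons that rule takes the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change and a gene symbol as name. Names made only of capitals and digits were read as clone names, which left out the gene F10. It adds the called members of the M2, M1, retinoid and receptor-signalling lists and up to 4 members of every other list with the largest change, and for the remaining comparisons it takes up to 8 called genes. The lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 27 lists of a comparison. The fry test asks whether a list's genes moved on balance in 1 direction, and its mixed form whether they changed in either direction. Members of each list were also counted after adjusting p over the list alone.

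To ask whether ATRA opposed the response to IL-13 without using an array on both sides, genes were chosen by IL-13 minus control at 1 time and their difference between IL-13 with ATRA and IL-13 was measured at the other time. Their median was ranked among 10000 random lists of the same size matched on mean signal, and shares of genes carry exact Clopper-Pearson 95% intervals, which cover counting error only. The fits, the list tests and this comparison were tested on simulated data. With 50 simulated genes changed at each size between IL-13 and control, limma called 14 at a log2 difference of 1, 40 at 2, 49 at 4 and 50 at 6, and 10 unchanged genes. With 1 list shifted by 1, camera called 2 lists. Of simulated genes higher with IL-13 and chosen at 12 h, 50.66% were opposed with no effect. With 200 genes raised by 3 and fully reversed the share was 74.12%. The simulated genes varied independently of each other, whereas the measured interferon-stimulated genes had an estimated correlation of 0.613. No background filter was applied to the simulated arrays. The simulation therefore cannot show how the list tests behave with correlated genes, or what the filter does to the share opposed.

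The alternatives were quantile normalization, normexp background correction (offset 50) of the raw signals with quantile normalization, the authors' log2 values, no filter on dim probes, a filter for probes well above background on all 8 arrays, all probes in place of 1 per gene, eBayes with trend and robust settings, no time term, time and slide as a random block, only the arrays of the groups compared, 1.5-fold in place of 2-fold, and each array left out in turn. The counts of calls shared by comparisons with no array in common were recomputed under the value and filter alternatives, a choice made after seeing the data. The signals of control spots were not used.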

Results

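Gene expression was measured on 8 arrays of RAW264.7 cells, a mouse macrophage-like line. The cells were untreated or treated with ATRA, a ligand of the retinoic acid receptors, with IL-13, a cytokine that drives alternative (M2) activation of macrophages, or with both. Each of the 4 treatments had 2 arrays, 1 at 12 h and 1 at 24 h. The labels call control and ATRA cells unpolarized, IL-13 cells M2 macrophages and cells given both agents M2 polarization suppressed. No treatment was replicated at the same time, so the agreement between 12 h and 24 h served as the replicate spread. Of the 15440 genes tested, every call in the treatment comparisons had the same sign at both times. The test itself favours such genes, since disagreement between the times is its spread.

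The first comparison asked what IL-13 alone did to the cells. It raised 9 of 21 measured markers of alternative activation. Cish, a feedback inhibitor of cytokine signalling, was at least 173-fold higher (adjusted p = 0.00176), and Arg1, the arginase of alternatively activated macrophages, was at least 37.1-fold higher (adjusted p = 0.0174), both from below the background limit in control cells. The mannose receptor Mrc1 rose by 5.19 ± 0.37 log2 units (adjusted p = 0.0174; 4.36 at 12 h and 6.02 at 24 h). The transcription factors Batf3 (4.04 ± 0.15, adjusted p = 0.00413) and Irf4 (3.39 ± 0.15, adjusted p = 0.00634) and the eosinophil-attracting chemokine Ccl24 (3.17 ± 0.42, adjusted p = 0.0443) rose as well.

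Of the 21 measured M2 markers, 9 rose and 0 fell over all genes tested, and 17 rose when adjusted over the list alone. Besides Arg1, Mrc1, Batf3, Irf4 and Ccl24 these 9 were Cd200r1 (2.45), the transcription factor Egr2 (2.38), the lectin Clec7a (2.05) and the scavenger receptor Cd36 (1.68). The list's median log2 difference was 1.86, also with Arg1 at its bound (camera adjusted p = 1.4e-13; adjusted p = 0.639 with an estimated correlation; fry adjusted p = 0.0144). Among the members that did not pass over all genes, Mgl2 was 2.58 higher (adjusted p = 0.0896), Il4i1 3.54 higher (adjusted p = 0.0951) and the cytokine Il10 1.55 higher (adjusted p = 0.0513). The list held 11 further genes that were not tested. Ear11 was not found on the array, and the others, among them Retnla, Ccl17 and Ccl22, had no probe that passed the filter in any treatment. The counts and the median therefore cover only the members that passed.

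**Figure D1:**
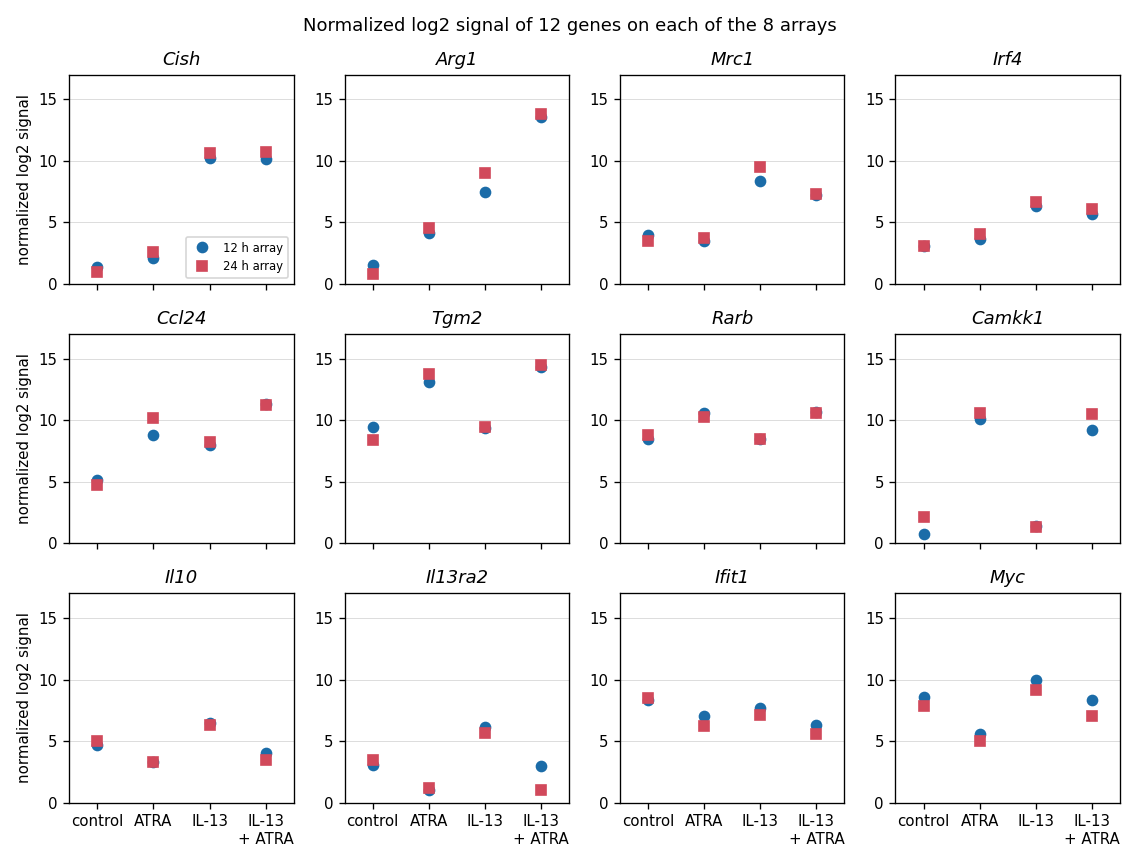
Normalized log2 signal (y axis) of 12 genes under the 4 treatments (x axis), with a circle for the 12 h array and a square for the 24 h array. Arg1 stood at 7.48 and 8.99 with IL-13 and at 13.57 and 13.84 with IL-13 and ATRA, while Mrc1 stood at 8.37 and 9.47 with IL-13 and at 7.24 and 7.32 with both.

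In the list of the IL-4 and IL-13 receptor and JAK-STAT pathway, Cish and Socs1 (2.61 ± 0.24), both feedback inhibitors, rose, 2 of 16 members over all genes and 4 higher with 1 lower when adjusted over the list alone. Camera did not call that list as a whole (adjusted p = 0.287, or 0.639 with an estimated correlation), while fry called it higher (adjusted p = 0.0218). Of 13 chemokines 3 rose, namely Ccl7 (4.19 ± 0.42, well above background on 1 of 2 control arrays), Ccl2 (3.06 ± 0.36) and Ccl24, and 8 rose with 1 lower when adjusted over the list alone (median 1.27, camera adjusted p = 0.000576; adjusted p = 0.639 with an estimated correlation). Of 8 dendritic cell genes 3 rose, namely the integrin Itgax (4.21 ± 0.31), Batf3 and Cd83 (0.96 ± 0.11), the same number as when adjusted over the list alone (median 0.19, camera adjusted p = 0.021; adjusted p = 0.639 with an estimated correlation). Batf3 also belongs to the M2 list, and a second probe of Itgax gave 2.68. The dendritic cell list lost its call without control replicate 1 (adjusted p = 0.0534) and without IL13 replicate 1 (adjusted p = 0.0777). Of 14 matrix and angiogenesis genes 4 rose, namely the growth factors Hbegf (4.48 ± 0.51, well above background on 1 of 2 control arrays), Vegfc (4.07 ± 0.48) and Pdgfa (1.04) and the protease inhibitor Timp1 (2.08 ± 0.17), and 5 when adjusted over the list alone (median 0.43, camera adjusted p = 0.00494; adjusted p = 0.639 with an estimated correlation). Of 11 genes of arginine and polyamine metabolism only Arg1 rose over all genes, and 3 did when adjusted over the list alone (median 0.32, camera adjusted p = 0.0273; adjusted p = 0.639 with an estimated correlation; adjusted p = 0.0777 without IL13 replicate 1). Of 13 antigen presentation genes the invariant chain Cd74 (1.77 ± 0.14) and H2-DMa (1.17 ± 0.16) rose, and 3 rose when adjusted over the list alone. Camera did not call this list (adjusted p = 0.237, or 0.639 with an estimated correlation), while fry called it higher (adjusted p = 0.0218).

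Interferon-stimulated genes were lower with IL-13. Their list had a median of −1.07, with 24 of 24 measured members lower, 3 called over all genes (Oas3, −2.10 ± 0.21, with −0.82 on a second probe; Oas2, −1.22; Stat2, −0.93) and 17 lower when adjusted over the list alone. The list's camera adjusted p was 5.8e-10, against adjusted p = 0.639 with an estimated correlation and a fry adjusted p of 0.0809. The median was −0.63 at 12 h and −1.47 at 24 h.

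Other genes that rose included Neb (at least 22.7-fold; adjusted p = 0.0228; its 5 other probes did not pass the filter), the vasoconstrictor peptide Edn1 (at least 5.43-fold; adjusted p = 0.00875) and the glutathione transferase Gstt4 (at least 3.74-fold; adjusted p = 0.0228). The coagulation factor gene F10, chosen after its values were seen, rose by 4.20 ± 0.43 (adjusted p = 0.0286). Genes that fell included the connexin Gja3 (at least 15.3-fold lower; adjusted p = 0.029; its 2 other probes were well above background on 0 arrays and gave 0.04 and 0.09), the receptor Pilrb1 (−3.87 ± 0.52, well above background on 1 of 2 IL-13 arrays), the oestrogen receptor Gper1 (−2.40 ± 0.24), the pro-apoptotic factor Bmf (−2.08 ± 0.28, with −0.95 and −1.89 on its other probes) and the lipoxygenase Alox5 (−1.87 ± 0.21). Among 16 macrophage identity genes Adgre1 (1.06 ± 0.13) rose and the fractalkine receptor Cx3cr1 (−1.21 ± 0.12) fell, with 1 higher and 2 lower when adjusted over the list alone (median −0.06, camera adjusted p = 0.689).

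In total 196 genes were called between IL-13 and control, 105 higher and 91 lower, and 3694 had an unadjusted p under 0.05. Quantile normalization gave 113 higher and 52 lower, and the authors' values gave 110 higher and 53 lower. At both times 202 genes were at least 2-fold higher and 245 at least 2-fold lower, while 19 changed 2-fold in opposite directions, and under quantile normalization 237 were higher and 191 lower. The 12 h and 24 h differences had a Pearson r of 0.54 and a Spearman rho of 0.495 across genes, which are not independent replicates. The count of calls was 2 without control replicate 2, 9 without control replicate 1, 41 without IL13 replicate 2, 72 without either ATRA array, 80 without either IL13_ATRA array and 357 without IL13 replicate 1. The call of Cish held without each of the 8 arrays, while Arg1 lost its call without control replicate 1 (adjusted p = 0.0548) and control replicate 2 (adjusted p = 0.105), as did Mrc1 (0.0764 and 0.105). The calls of Gper1, Oas3, Cd36, H2-DMa, Cx3cr1, Adgre1 and Cd83 were lost in 7 of the 8 refits without 1 array, and that of Dhrs3 in all 8. The count was 1 with no filter on dim probes, 9 with only the arrays of the groups compared, 536 with normexp correction and 606 with trend and robust settings. Normexp correction, whose offset shrinks differences of dim probes, gave a log2 difference of 2.90 for Mrc1. Cd36 lost its call under 6 of the 10 alternatives that kept all 8 arrays.

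The second comparison asked what ATRA did without IL-13. Camkk1, a calcium-dependent kinase, was at least 163-fold higher (adjusted p = 0.00414), the organic anion transporter Slco2b1 at least 57-fold (adjusted p = 0.0178), Col14a1 at least 25.8-fold on the probe used (adjusted p = 0.0045; −0.56 on a second probe, which was well above background on 1 of 8 arrays) and the gelatinase Mmp9 at least 20.7-fold higher (adjusted p = 0.00571). Transglutaminase Tgm2 rose by 4.50 ± 0.39 log2 units (adjusted p = 0.0182; 3.64 at 12 h and 5.36 at 24 h), the complement component C1qa by 5.32 ± 0.72 (adjusted p = 0.0406) and the lipogenic transcription factor Mlxipl by 5.63 ± 0.35 (adjusted p = 0.0088), with 2.499 on a second Mlxipl probe.

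Of 14 retinoid genes 4 rose, namely Tgm2, the retinaldehyde reductase Dhrs3 (2.72 ± 0.19), the receptor Rarb (1.81 ± 0.18; 2.14 at 12 h and 1.47 at 24 h) and the nuclear receptor cofactor Nrip1 (1.76 ± 0.15). When adjusted over the list alone 5 rose and 3 fell, and the list was not called (median 0.11, camera adjusted p = 0.124). Of 13 chemokines 4 rose, namely Ccl24 (4.54 ± 0.42), Ccl6 (3.03 ± 0.20), Ccl12 (2.62 ± 0.25, well above background on 1 of 2 control arrays) and Cxcl14 (2.56 ± 0.18), and 6 rose with 2 lower when adjusted over the list alone (median 1.03, camera adjusted p = 0.000149; adjusted p = 0.933 with an estimated correlation). Of 16 genes of the unfolded protein response 0 were called by limma over all genes and 1 rose when adjusted over the list alone (median 0.34, camera adjusted p = 0.00319; adjusted p = 0.933 with an estimated correlation). Its largest differences were those of Sesn2 (0.73, adjusted p = 0.354) and Pdia4 (0.68, adjusted p = 0.0803). The unfolded protein response list lost its call without control replicate 1 (adjusted p = 0.272) and without ATRA replicate 2 (adjusted p = 0.0544).

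Of 24 interferon-stimulated genes 7 fell over all genes and 22 when adjusted over the list alone. The list's median was −1.59, and 24 of 24 members were lower (camera adjusted p = 7.0e-19; adjusted p = 0.933 with an estimated correlation; fry adjusted p = 0.135). Among them were Oasl2 (−2.03 ± 0.28), Ifit3 (−1.97 ± 0.23), Mx2 (−1.76) and Ifit1 (−1.81).

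The M2 list was split, with a median of 0.20 or, with bounds in place of fitted values, of 0.096. Over all genes 4 members rose (Ccl24, Tgm2, Clec7a at 2.04 ± 0.14 and Batf3 at 0.99 ± 0.15) and 2 fell (the transcription factor Klf4, −2.34 ± 0.26, and Il10, −1.54 ± 0.22, well above background on 1 of 2 ATRA arrays), and 7 rose and 3 fell when adjusted over the list alone (median 0.20, camera adjusted p = 0.0645). Arg1 did not pass (adjusted p = 0.0558) and was at least 2.45-fold above the background limit of control cells. It passed with time as a random block (adjusted p = 0.0336), trend and robust settings (0.0338), no time term, only the arrays of the groups compared, and without either IL13 array. The interleukin-4 receptor chain Il4ra rose by 1.39 ± 0.20.

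**Figure D2:**
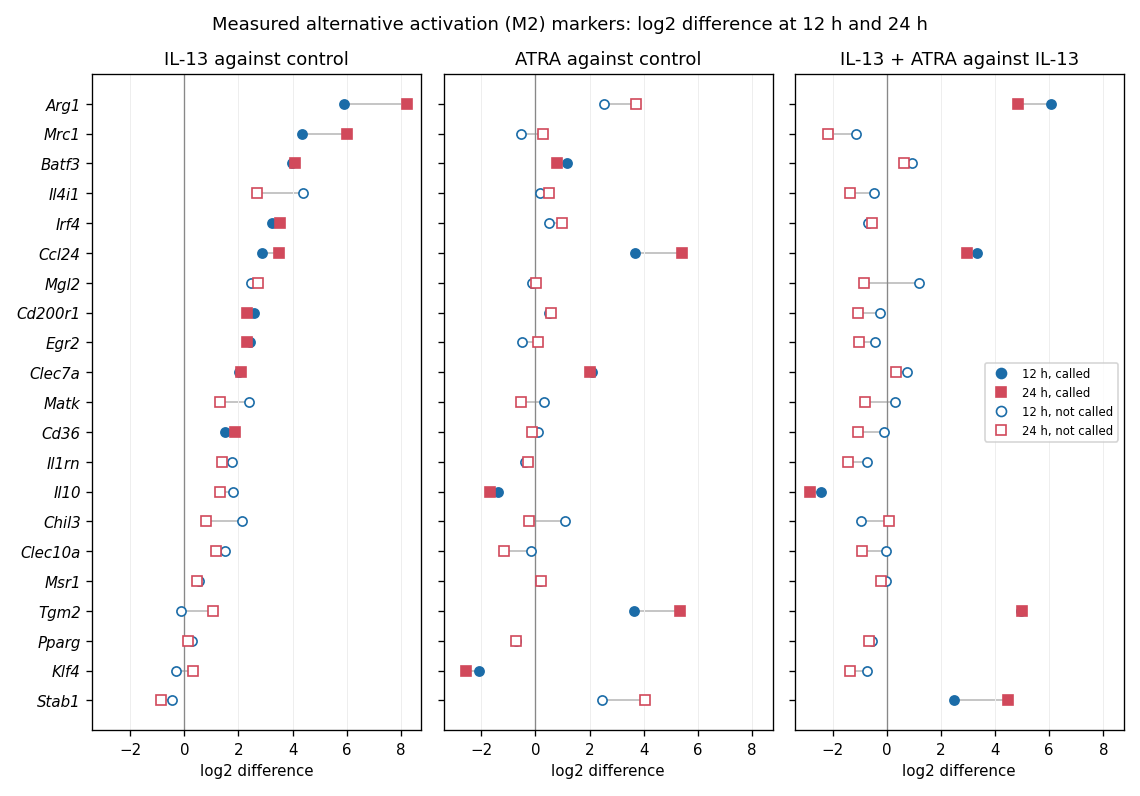
Log2 differences (x axis) of the measured M2 markers (y axis) at 12 h (circles) and 24 h (squares) in 3 comparisons, with filled points for genes called over all genes. IL-13 against control had 9 called higher and 0 lower, ATRA against control 4 higher and 2 lower, and IL-13 with ATRA against IL-13 4 higher and 1 lower.

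ATRA lowered Myc, a proliferation-driving transcription factor, by 2.95 on the log2 scale (adjusted p = 0.0088; −3.02 at 12 h and −2.88 at 24 h), which fell by 2.77 and by 1.96 on its other probes. Ocstamp (−3.82 ± 0.33, with −2.73 on a second probe) and Dcstamp (−2.06 ± 0.30), which act in osteoclast fusion, fell, whereas Mmp9 and the carbonic anhydrase Car2 (1.99 at 12 h and 2.01 at 24 h), both also osteoclast genes, rose. Of 12 osteoclast genes these 2 rose and 2 fell, with 2 higher and 4 lower when adjusted over the list alone. Other genes that fell included Gja3 (at least 15.3-fold lower, with 0.14 and 0.21 on its dim other probes), Kirrel3 (at least 11.5-fold lower, with −2.28 on a second probe), Pilrb1 (at least 7.35-fold lower), the signalling regulator Rgs16 (−3.42 ± 0.40), Zbtb32 (−3.36 ± 0.50) and Oit3 (−2.71 ± 0.13, with −0.53 on a dim second probe). The heat shock gene Hspa1a (at least 1.48-fold lower) and the immediate early genes Fos (−1.38) and Dusp1 (−1.28) also fell, 3 of 17 members of their list, while 3 rose and 3 fell when adjusted over the list alone.

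In total 287 genes were called between ATRA and control, 139 higher and 148 lower, and 2339 had an unadjusted p under 0.05. At both times 161 genes were at least 2-fold higher and 240 at least 2-fold lower, with 6 opposite, and the times had a Pearson r of 0.631 and a Spearman rho of 0.468 across genes. The count of calls was 1 without control replicate 2, 19 without ATRA replicate 2, 27 without ATRA replicate 1, 63 without control replicate 1, 74 without either IL13_ATRA array and 171 without either IL13 array, and the number of lists was 5 instead of 3 without ATRA replicate 1. Camkk1 lost its call without control replicate 2 (adjusted p = 0.0659), and Tgm2 without either ATRA array (0.0592 and 0.0845) or control replicate 2 (0.0739). The calls of Il4ra, Il10, Batf3, Zbtb32, Dcstamp and Hspa1a were lost without each of the 8 arrays in turn, and that of C1qa in 7 of the 8 refits. Batf3 also lost its call under 6 of the 10 other alternatives. With no filter on dim probes limma called 0 genes (2177 at an unadjusted p under 0.05), and it called 433 with the filter for all 8 arrays, 567 with normexp correction and 630 with trend and robust settings.

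The third comparison asked what ATRA did in the presence of IL-13, where the labels call M2 polarization suppressed. Its effect on M2 markers went both ways. Of the M2 members called here, Arg1 and Ccl24 had also been called higher with IL-13 alone, while Tgm2, Stab1 and Il10 had not. Tgm2 is also in the retinoid list. Arg1 was 5.47 ± 0.50 log2 units higher with both agents than with IL-13 (adjusted p = 0.0168; 6.08 at 12 h and 4.85 at 24 h), Tgm2 4.99 ± 0.39 higher (adjusted p = 0.0134), the scavenger receptor Stab1 3.49 ± 0.56 higher (adjusted p = 0.0481) and Ccl24 3.15 ± 0.42 higher (adjusted p = 0.0333). Il10, an anti-inflammatory cytokine, fell by 2.64 (adjusted p = 0.0152; −2.43 at 12 h and −2.84 at 24 h). The decoy receptor Il13ra2 was at least 6.31-fold lower (adjusted p = 0.0368) and the receptor chain Il13ra1 fell by 1.18 (adjusted p = 0.0346).

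The remaining M2 markers did not pass over all genes. The log2 difference was −1.64 ± 0.37 for Mrc1 (adjusted p = 0.1; −1.13 at 12 h and −2.16 at 24 h), −0.60 ± 0.15 for Irf4 (adjusted p = 0.125), −0.74 for Egr2, −0.58 for Cd36 and −0.66 for Cd200r1. Batf3 and Clec7a, which IL-13 alone had also raised, were higher in sign. Of all 21 measured members, called or not, 7 were higher in sign and 14 lower. Mrc1 passed as lower with normexp correction (adjusted p = 0.0419), with trend and robust settings (0.0465) and without IL13 replicate 1 (0.0391). With 4 members called higher and 1 lower, or 6 and 6 when adjusted over the list alone, the list had a median of −0.46 and a mean of 0.33, while camera's direction was lower (adjusted p = 0.808). A second probe of Stab1 gave a smaller difference of 1.98, and it was 1.02 higher with IL-13 alone where the probe used gave −0.66. Stab1 lost its call under 6 of the 10 alternatives that kept all 8 arrays. Of 16 members of the IL-13 receptor and JAK-STAT list 0 rose and 2 fell (1 and 2 when adjusted over the list alone).

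With IL-13 present too, ATRA raised Camkk1 at least 104-fold (adjusted p = 0.00308) and Mmp9 by 5.09 ± 0.33, well above background on 1 of 2 IL-13 arrays. The milk protein Csn3 was at least 76.3-fold higher on the probe used (adjusted p = 0.0148), and its other probe gave 2.05. The heparan sulfate enzyme Ndst1 was 5.24 ± 0.40 higher on the probe used, and its 3 other probes gave 0.30, 2.89 and 4.56. Of 14 retinoid genes 4 rose (Tgm2, Nrip1 by 2.27 ± 0.15, Rarb by 2.17 ± 0.18 and Dhrs3 by 1.58 ± 0.19) and 5 rose when adjusted over the list alone (median 0.66, camera adjusted p = 0.0281; adjusted p = 0.937 with an estimated correlation; fry adjusted p = 0.0449). That call was lost without IL13 replicate 1 (adjusted p = 0.0772), IL13 replicate 2 (adjusted p = 0.0526) or IL13_ATRA replicate 2 (adjusted p = 0.0969). Of 13 chemokines 4 rose (Ccl24, Cxcl14 by 2.16 ± 0.18, Ccl12 by 2.07 ± 0.25 and Ccl6 by 1.76 ± 0.20) and Cxcl16 fell by 1.49, with 5 higher and 3 lower when adjusted over the list alone. The median of the chemokines was −0.03 and their mean 0.48 (camera adjusted p = 0.441).

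Interferon-stimulated genes were lower again, by a median of −0.91, with 22 of 24 members lower, 4 called over all genes and 18 when adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.937 with an estimated correlation; fry adjusted p = 0.16). Ifit3 fell by 1.63 and Ifit1 by 1.46, and Ifit1 lost its call under 6 of the 10 alternatives that kept all 8 arrays. Of 18 cholesterol synthesis genes limma called 0 over all genes and 0 when adjusted over the list alone, although camera called the list higher (median 0.17, adjusted p = 0.0205; adjusted p = 0.937 with an estimated correlation). That call was lost without IL13 replicate 2 (adjusted p = 0.191) and without IL13_ATRA replicate 2, where the median was −0.02 (adjusted p = 0.0969). Its largest members were the transcription factor Srebf2 (0.90, adjusted p = 0.224, with −0.14 to 0.49 on its other probes) and Lss (0.52, adjusted p = 0.104).

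**Figure D3:**
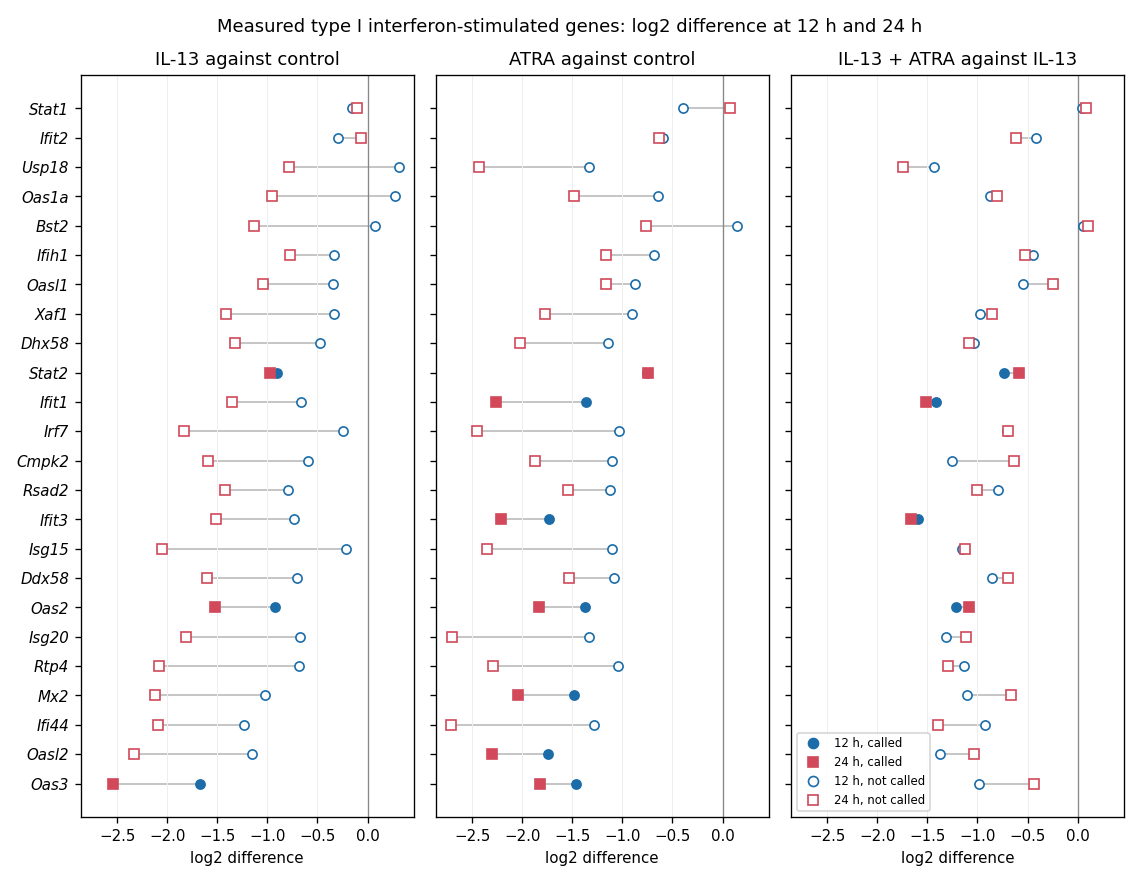
Log2 differences (x axis) of the 24 measured interferon-stimulated genes (y axis) at 12 h (circles) and 24 h (squares) in 3 comparisons, with filled points for genes called over all genes. All 24 were lower in the fitted comparisons of IL-13 and of ATRA with control, and 22 were lower with IL-13 and ATRA than with IL-13.

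Other genes that fell included Neb (at least 19.3-fold lower), Kirrel3 (at least 8.46-fold lower, with −2.04 on a second probe), Smim5 (at least 2.79-fold lower), Rgs16 (−3.76 ± 0.40), Vegfc (−3.32 ± 0.48), Zbtb32 (−3.09 ± 0.50), Ocstamp (−2.47 ± 0.33, with −2.21 on a second probe), Fos (−2.04 ± 0.18), Dcstamp (−2.03 ± 0.30) and the Fc receptor Fcgr3 (−1.18 ± 0.15).

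In total 407 genes were called between IL-13 with ATRA and IL-13, 178 higher and 229 lower, and 2944 had an unadjusted p under 0.05. At both times 177 genes were at least 2-fold higher and 248 at least 2-fold lower, with 27 opposite, and the times had a Pearson r of 0.551 and a Spearman rho of 0.452 across genes. The count of calls was 15 without IL13_ATRA replicate 2, 59 without IL13 replicate 2, 91 without IL13_ATRA replicate 1, 119 without either control array and 150 without either ATRA array, and the number of lists was 1 instead of 3 without IL13 replicate 2. It was 7 with no filter on dim probes, 13 with only the arrays of the groups compared, 734 with normexp correction and 817 with trend and robust settings. Arg1 lost its call without either IL13_ATRA array (adjusted p = 0.0726 and 0.115), as did Tgm2 (0.0547 and 0.0928), which also lost it without IL13 replicate 2 (0.0607). Il10 lost its call without IL13 replicate 2 (0.0672) and IL13_ATRA replicate 2 (0.0666). The calls of Ccl24 and Stab1 held in 2 and 1 of the 8 refits without 1 array, and the highest adjusted p was 0.163 for Ccl24 and 0.252 for Stab1, both without IL13_ATRA replicate 2. The calls of Ccl6 and Cd83 were lost in all 8 refits, and those of Il13ra2, Vegfc, Ocstamp and Fcgr3 in 7 of the 8.

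A further comparison asked whether ATRA moved IL-13-responsive genes back towards control. Of 352 genes at least 2-fold higher with IL-13 at 12 h, 69% (95% interval 63.9% to 73.8%) were lower with IL-13 and ATRA than with IL-13 at 24 h, against 50.9% of all genes. Their median was −0.56, where random lists gave −0.14 to 0.08. Of 321 genes chosen at 24 h, 61.1% (55.5% to 66.4%) were lower at 12 h against 54.2% of all genes, with a median of −0.19 against −0.12 to 0.09. Of 926 genes at least 2-fold lower with IL-13 at 12 h, 49.2% were higher with ATRA at 24 h against 49.1% of all genes, and their median of −0.02 lay at percentile 99.5 of random lists (−0.13 to 0.00). Of 846 chosen at 24 h, 57.2% (53.8% to 60.6%) were higher against 45.8%, and their median of 0.08 lay at percentile 100 (−0.07 to 0.03).

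Among the 105 genes called higher with IL-13, 24 were called lower when ATRA was added and 78 were lower in sign, with a median of −0.53, but these counts share the IL-13 arrays. The 5 called higher were Arg1, Ccl24, Dhrs3, Cd83 and the thromboxane synthase Tbxas1 (2.81 ± 0.17), the last chosen after its values were seen. Of the 91 called lower with IL-13, 9 were called higher with ATRA and 9 were called lower. With no filter on dim probes the share for IL-13-raised genes chosen at 12 h was 46.7%, and with a 1.5-fold limit it was 59.5%. A gene that passed the filter only through its IL-13 arrays was selected for a high IL-13 signal at both times. That favours a lower value with ATRA, and its part in the share was not tested. For IL-13-lowered genes chosen at 24 h the share turned to 39.5% with no filter on dim probes, and for those chosen at 12 h it was 70.8% with normexp correction.

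IL-13 was also compared with both agents present against ATRA alone. Arg1 was 9.39 ± 0.50 log2 units higher (adjusted p = 0.00972, and 0.0621 to 0.0826 without ATRA replicate 1 or either IL13_ATRA array), Cish at least 156-fold higher (adjusted p = 0.00188), Itgax 4.06 ± 0.31 higher (adjusted p = 0.0229), Ccl7 3.88 ± 0.42 higher (adjusted p = 0.0481, lost in all 8 refits without 1 array), Batf3 3.84 higher, Mrc1 3.67 higher and Irf4 2.04 higher. Protocadherin Pcdhb11 was at least 5.42-fold and the antizyme inhibitor Azin2 at least 3.63-fold higher. Of 21 M2 markers 4 rose and 0 fell, and 16 rose when adjusted over the list alone (median 1.30, camera adjusted p = 9.1e-16; adjusted p = 0.599 with an estimated correlation; fry adjusted p = 0.0245).

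Of 24 interferon-stimulated genes limma called 0 over all genes and 3 lower when adjusted over the list alone (median −0.55, camera adjusted p = 3.1e-05; adjusted p = 0.737 with an estimated correlation). Of 11 arginine and polyamine genes Arg1 rose and 3 did when adjusted over the list alone (median 0.23, camera adjusted p = 0.0271; adjusted p = 0.713 with an estimated correlation). The number of called lists was 8 instead of 3 without ATRA replicate 2 and 6 without IL13_ATRA replicate 2.

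In total 56 genes were called between IL-13 with ATRA and ATRA, 41 higher and 15 lower, and 1998 had an unadjusted p under 0.05. At both times 124 genes were at least 2-fold higher and 112 at least 2-fold lower, with 16 opposite, and normexp correction gave 52 higher and 18 lower. The times had a Pearson r of 0.511 and a Spearman rho of 0.493 across genes. The count of calls was 3 without IL13_ATRA replicate 1, 5 without either control array or without ATRA replicate 1, 11 without IL13_ATRA replicate 2 and 24 without ATRA replicate 2. It was 2 with only the arrays of the groups compared, 4 with no filter on dim probes, 85 with time as a random block, 88 with the filter for all 8 arrays, 109 with normexp correction and 167 with trend and robust settings.

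Comparisons with no array in common shared calls. IL-13 calls without and with ATRA shared 34 genes higher and 9 lower, and the 2 sets of differences had a Pearson r of 0.614 and a Spearman rho of 0.685 across genes. ATRA calls without and with IL-13 shared 102 genes higher and 98 lower, with a Pearson r of 0.639 and a Spearman rho of 0.585. Both comparisons of a pair used the same residual spread of each gene, so their calls were not independent. With no filter on dim probes these 4 counts were 1, 0, 0 and 0. The 105 genes called higher with IL-13 had a median of 2.05 without ATRA and of 1.22 with ATRA, smaller in 90 of them. They were selected on the first value, which tends to make the second smaller. The 41 genes called higher with ATRA, selected the other way, had a median of 2.23 with ATRA and of 2.05 without, smaller in 20 of them, so how much of the first decrease comes from selection stays open.

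The interaction asked whether the effect of IL-13 differed with ATRA. Mpdz, a scaffold protein of cell junctions (adjusted p = 0.0213), and the developmental transcription factor Pax9 (adjusted p = 0.0342) passed and were well above background only with both agents. 1700025L06Rik, chosen after its values were seen since it has no gene symbol, was well above background only with IL-13 alone (adjusted p = 0.0309). By limma its call was lost with quantile normalization (adjusted p = 0.102), the authors' values (0.0987), normexp correction (0.89) and trend and robust settings (0.249). No size of the interaction is given for these 3 genes, since 3 of the 4 treatments were not well above background on either array. Their p-values rest on the same dim signals and so do not measure the spread of expression alone. By limma, Mpdz and Pax9 lost their calls with normexp correction (adjusted p = 0.0657 and 0.41) and with trend and robust settings (0.0545 and 0.0882). Against IL-13 alone Mpdz was at least 23.6-fold and Pax9 at least 20.8-fold higher with both agents on the probes used. The dim other probes of Mpdz gave 0.01 and −0.47. The interaction was −1.35 for Irf4 (adjusted p = 0.584) and for Clec7a −1.51 (adjusted p = 0.488).

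Camera called 6 lists for the interaction. The M2 markers had a median of −0.52 (adjusted p = 0.00112; 2 members lower when adjusted over the list alone), the M1 markers −0.23 (adjusted p = 0.0268), the matrix genes −0.29 (adjusted p = 0.0268), the chemokines −0.79 (adjusted p = 2.2e-06), the interferon-stimulated genes 0.45 (adjusted p = 3.0e-07; 24 of 24 positive) and the cholesterol synthesis genes 0.15 (adjusted p = 0.0272). The adjusted p = 0.76 with an estimated correlation for the cholesterol synthesis genes and 0.678 for the other 5, and fry called 0 lists (lowest adjusted p = 0.902). Over all genes limma called 0 of their members, and adjusted over the list alone it called 0 in the 5 lists other than the M2 markers. The 15 measured M1 markers, which lacked Nos2 and Il6, had 0 members called by limma over all genes in any comparison, against 3 higher and 4 lower with IL-13 when adjusted over the list alone. The chemokine call held without each of the 8 arrays. The M2 call was lost without IL13 replicate 2 (adjusted p = 0.0927) or IL13_ATRA replicate 2 (0.223), the interferon call without control replicate 2 (0.226), and the M1, matrix and cholesterol calls without 5, 5 and 4 of the 8 arrays.

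In total limma called 3 genes for the interaction, 2 higher and 1 lower, and 564 had an unadjusted p under 0.05. At both times 104 genes had a positive and 75 a negative interaction of at least 2-fold, with 44 opposite, against 86 and 94 under quantile normalization and 7 and 12 with normexp correction, and the times had a Pearson r of 0.249 and a Spearman rho of 0.158 across genes. The count of calls was 0 without control replicate 1, IL13 replicate 1 or either IL13_ATRA array, 1 without control replicate 2 or ATRA replicate 1, 7 without IL13 replicate 2 and 8 without ATRA replicate 2. It was 0 with no filter on dim probes, the filter for all 8 arrays or trend and robust settings (846, 396 and 450 genes at an unadjusted p under 0.05), and 1 with normexp correction or with no time term. Pax9 lost its call without each of the 8 arrays in turn, and Mpdz without either control array, either IL13_ATRA array or IL13 replicate 1 (adjusted p from 0.0699 to 0.199). The number of lists was 3 without control replicate 2 or ATRA replicate 2 and 2 without IL13 replicate 2 or IL13_ATRA replicate 2.

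Between 24 h and 12 h, which cannot be told apart from the slides, limma called 0 genes, with 1880 at an unadjusted p under 0.05 and a lowest adjusted p of 0.28. Normexp correction called 2 genes and trend and robust settings called 3. A difference between times in the effect of IL-13 was called for 0 genes (1535 at an unadjusted p under 0.05, lowest adjusted p = 0.465) and in the effect of ATRA for 0 genes (1478, lowest adjusted p = 0.503), with 1 residual degree of freedom. With trend and robust settings these counts were 2 and 146.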

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

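The tests of technical explanations in this part were chosen after the result was seen, except the rank of the interferon-stimulated genes among matched random lists, whose limits were set before the rank was computed but when the list's medians were known.

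For 3 genes limma called the interaction of IL-13 and ATRA. Mpdz had a fitted interaction of 6.603, with signals of 7.996 at 12 h and 7.36 at 24 h with both agents and of 0.72 to 1.36 on the other 6 arrays. Pax9 had a fitted interaction of 5.499, with signals of 7.03 and 7.95 with both agents and of 0.82 to 2.01 elsewhere. 1700025L06Rik had a fitted interaction of −4.235, with signals of 5.47 and 4.75 with IL-13 alone and of 0.92 to 2.15 on the other arrays. The lower signals were not well above background, so these fitted sizes are neither measured sizes nor bounds. The p-values of the calls rest on the same signals.

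A defect of 1 array or slide was tested for Mpdz and Pax9 from the gap between the lower array with both agents and the background limit of the other 6 arrays. The gap was at least 3.68 for Mpdz and 3.355 for Pax9 on the log2 scale, on arrays of different slides. Both genes passed the filter only because both arrays with IL-13 and ATRA were well above background. The call also favours agreement between the times. A signal on both arrays was therefore largely fixed by this selection, so the gap cannot decide on such a defect. Of the other probes of Mpdz 0 were well above background on any array. They gave 0.01 and −0.47 between IL-13 with ATRA and IL-13, and so did not show the rise of the probe used. A signal of the probe used and not of the transcript therefore cannot be told apart from expression of Mpdz. Pax9 had 0 other probes, so a signal of its probe and not of its transcript cannot be told apart from expression of Pax9. An effect of the combination on these genes stays open, and with normexp correction the adjusted p was 0.0657 for Mpdz and 0.41 for Pax9.

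Arg1, a marker of alternative activation, was higher with both agents than with IL-13 alone on arrays whose labels call M2 polarization suppressed. Exchanged labels between the IL-13 arrays and the arrays with both agents were tested on the 139 genes that ATRA alone raised, and 97.12% of them were higher on the arrays labelled with both agents at each time, which argues against an exchange. The scaling between arrays does not account for it, since the lowest Arg1 difference under quantile normalization, normexp correction and the authors' values was 5.087. The array held 0 other Arg1 probes, so a signal of the Arg1 probe and not of the Arg1 transcript cannot be told apart from expression. An effect of ATRA on Arg1 in the presence of IL-13 may account for the difference and stays a hypothesis.

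Interferon-stimulated genes were lower with IL-13, with ATRA and with both. High levels on the control arrays alone would leave no difference between the other arrays, but the list's median was −0.9053 between IL-13 with ATRA and IL-13, which uses no control array, with −0.98 at 12 h and −0.83 at 24 h. A trend of the scaling with the brightness of probes would move matched lists alike, but the list's median lay at percentile 0 of 10000 matched random lists in each of the 4 treatment comparisons. These values are in line with a lower interferon response in cells given either agent, as a hypothesis, while differences between the cultures in cell density or handling were not measured and stay open.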

How the results depend on the processing

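The alternatives were chosen before the data were examined, except the recounts of shared calls, which were chosen after seeing the data. The direction of named genes and lists held more often than their calls. Of the values of named genes under alternatives that kept all 8 arrays, 1090 stayed on their side of the threshold, 316 lost their call, 6 gained one and 1 reversed. Named genes that an alternative's filter removed are not in these counts. With the filter for all 8 arrays only 26, 29 and 27 values remained in the first 3 comparisons, and all of these stayed. With 1 array left out, where the lone array of a treatment is assumed to vary like the other groups, 526 stayed, 654 lost their call, 3 gained one and 1 reversed. For called lists 97 calls stayed and 50 were lost under the other alternatives, all in the same direction by the test used, and 141 stayed and 27 were lost with 1 array left out. In every scaling alternative the median of all genes stayed within 0.04 log2 units of 0. Signal over background limits what dim groups can show, since folds from below background are bounds only.

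Counts of called genes are given in the order IL-13 against control, ATRA against control, IL-13 with ATRA against IL-13, IL-13 with ATRA against ATRA, interaction, 24 h against 12 h. Normexp correction gave 536, 567, 734, 109, 1 and 2. With no filter on dim probes, 27321 genes were tested, and the counts were 1, 0, 7, 4, 0 and 0. The 3 counts of 0 had 2177, 846 and 1876 genes at an unadjusted p under 0.05 by limma. The filter for probes well above background on all 8 arrays gave 433 for ATRA against control, 88 for IL-13 with ATRA against ATRA and 0 for the interaction (396 at an unadjusted p under 0.05), and it removed Mpdz and Pax9 by construction. Trend and robust settings gave 606, 630, 817, 167, 0 (450 at an unadjusted p under 0.05) and 3, and they gave 2 genes for a difference between times in the effect of IL-13 and 146 for ATRA. Trend and robust settings kept 173, 267, 370 and 53 of the calls in the 4 treatment comparisons, and normexp correction kept 132, 233, 326 and 43. Without a time term the interaction had 1 called gene, and with time and slide as a random block IL-13 with ATRA against ATRA had 85. With only the arrays of the groups compared, which left 1 residual degree of freedom, the counts were 9 for IL-13 against control, 13 for IL-13 with ATRA against IL-13 and 2 for IL-13 with ATRA against ATRA. The cause of the other changes was not tested.

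With 1 array left out the counts ranged from 2 (without control replicate 2) to 357 (without IL13 replicate 1) for IL-13 against control and from 1 (without control replicate 2) to 171 (without either IL13 array) for ATRA against control. They ranged from 15 (without IL13_ATRA replicate 2) to 516 (without IL13 replicate 1) for IL-13 with ATRA against IL-13, from 3 (without IL13_ATRA replicate 1) to 45 (without either IL13 array) for IL-13 with ATRA against ATRA, from 0 to 8 (without ATRA replicate 2) for the interaction and from 0 to 0 for 24 h against 12 h (1320 to 1727 at an unadjusted p under 0.05). The number of called lists ranged from 4 to 8, from 2 to 5, from 1 to 3, from 3 to 8 and from 2 to 9 in the first 5 comparisons. These fits had 2 residual degrees of freedom in place of 3.

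Genes at least 2-fold different the same way at both times, in the order of the first 5 comparisons, numbered 155, 171, 166, 70 and 19 with normexp correction, whose offset shrinks differences of dim probes. They numbered 701, 649, 688, 479 and 780 with no filter on dim probes, 253, 239, 240, 123 and 54 with the filter for all 8 arrays, and 1273, 985, 1097, 745 and 507 with a 1.5-fold limit, where the limits themselves set the number that can pass.

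For genes raised by IL-13 and chosen at 12 h, the share opposed by ATRA turned to 46.73% with no filter on dim probes and was 59.49% with a 1.5-fold limit. For genes lowered by IL-13 and chosen at 12 h it was 70.79% with normexp correction, 56.14% with quantile normalization, 55.87% with the authors' values and 53.18% with the filter for all 8 arrays. For those chosen at 24 h it was 63.57% with normexp correction and 53.26% with a 1.5-fold limit, and it turned to 39.49% with no filter on dim probes. The cause was not tested.

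Camera with an estimated correlation called 0 lists in each of the first 5 comparisons, and fry called 7, 0, 2, 4 and 0 lists. In its mixed form, for changes in either direction, fry called 21, 18, 22, 17 and 0 lists. With no filter on dim probes camera called 5 lists for ATRA against control and 3 for the interaction. Pcsk5 reversed to 1.893 (adjusted p = 0.728) between IL-13 with ATRA and IL-13 with no filter on dim probes, where a different probe was used. Tgm2, not called between IL-13 and control, ranged from −0.2112 to 1.148 with 1 array left out and reversed without control replicate 2. Of the 20 recounts of shared calls 10 moved, among them all 4 with no filter on dim probes, which gave 1, 0, 0 and 0 in place of 34, 9, 102 and 98.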

Other observations

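The tests in this part were chosen after the results were seen, except that the rule for the direction of ATRA's effect was written down before its values were computed, when the correlation over all genes was already known.

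Some lists fixed for other functions held genes that moved in opposite directions with ATRA. Among 14 LXR target genes, which govern cholesterol efflux, ATRA raised the transporter Abca1 (2.01 ± 0.21) and lowered the LDL receptor-degrading ligase Mylip (−1.40 ± 0.16), 1 higher and 1 lower over all genes and 3 and 2 when adjusted over the list alone (median −0.03, mean 0.14, camera's direction higher, adjusted p = 0.882). With IL-13 present ATRA raised Abca1 by 2.05 and lowered Mylip (−1.53) and the LXR receptor gene Nr1h3 (−1.03, a call lost in all 8 refits without 1 array). Among 20 lysosome and phagocytosis genes ATRA lowered Cd300a (−1.64 ± 0.19, a call lost in all 8 refits without 1 array), and 2 members were higher and 1 lower when adjusted over the list alone (median 0.16, camera adjusted p = 0.121). C1qb, chosen after its values were seen, rose by 3.73 ± 0.48 with ATRA beside C1qa, and Ptgs1, chosen in the same way, by 4.33 ± 0.29. Among 12 osteoclast genes the list median was 0.00 with ATRA and the mean 0.10, while camera's direction was lower (adjusted p = 0.916), and among 17 immediate early and heat shock genes it was −0.04 (camera adjusted p = 0.822).

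Lists of basic cell functions held few calls. With IL-13, limma called 0 over all genes among 30 cell cycle genes (median 0.14, camera adjusted p = 0.0897), 12 p53 targets and cell cycle inhibitors (−0.09, 0.876), 20 genes of glycolysis and hypoxia (−0.05, 0.538) and 12 housekeeping genes (0.08, 0.574), and 0 in each when adjusted over the list alone. With ATRA, which lowered Myc, the cell cycle genes had a median of 0.00 (camera adjusted p = 0.882) with 0 calls over all genes and over the list alone. Of 16 PPAR and fatty acid oxidation genes Cd36 rose with IL-13 over all genes and 2 did when adjusted over the list alone (median 0.17). Camera did not call this list (adjusted p = 0.107, or 0.639 with an estimated correlation), while fry called it higher (adjusted p = 0.0218). Markers of other cell types were mostly under background. With IL-13, limma called 0 over all genes and 0 over the list alone among the 5 measured of 13 granulocyte genes (median −0.24, camera adjusted p = 0.803), 4 of 10 T cell genes (−0.36, 0.574), 2 of 9 B cell genes (−0.22, 0.803), 2 of 10 fibroblast genes (−0.67, 0.32) and 3 of 10 epithelial genes (0.09, with camera's direction lower, 0.891). In the T cell list Cd28 rose by 1.98 ± 0.23 with ATRA, a call lost in all 8 refits without 1 array, and by 1.76 with ATRA in the presence of IL-13, well above background on 1 of 2 IL-13 arrays. In both comparisons limma called 0 members of the other 4 lists over all genes.

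Genes that IL-13 raised went up or down after ATRA was added, and the hypothesis was tested that ATRA acts on an IL-13-raised gene in the direction in which it acts without IL-13. Among genes at least 2-fold higher with IL-13 at 1 time, Spearman's rho across genes at the other time between ATRA minus control and IL-13 with ATRA minus IL-13 was 0.5423 for the 321 genes chosen at 24 h and 0.543 for the 352 chosen at 12 h. Over all genes rho was 0.377 and 0.629, and genes are not independent replicates. Of the 55 chosen at 12 h that ATRA alone raised at least 2-fold, 74.5% were higher with both agents than with IL-13, and of the 53 that it lowered, 92.5% were lower. Of the 171 that ATRA alone moved little, 73.1% were lower (median −0.45), against 50.9% of all genes. Of the genes chosen at 24 h, 82.9% of the 41 that ATRA alone raised were higher and 93% of the 43 that it lowered were lower, while 59.2% of the 157 that it moved little were lower (median −0.09), against 54.2% of all genes. ATRA's own direction thus went with which IL-13-raised genes moved up or down. These values do not show that it accounts for the net opposition to IL-13. Genes that ATRA alone moved little were lower about as often as all chosen genes. The shares were 73.1% against 69% for the choice at 12 h and 59.2% against 61.1% for the choice at 24 h. What accounts for the opposition stays open.

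With 24 h and 12 h exchanged within treatments the 8 arrays made 8 splits, too few for a share under 0.05. The real split gave 0 called genes by limma (1880 at an unadjusted p under 0.05) and the highest of the others gave 0 (at most 896 at an unadjusted p under 0.05). With a real count of 0 all 8 of 8 splits had to give as many, so this count tests nothing. Among all 35 splits of the 8 arrays into 4 and 4, fitted without treatment, the highest count was 664 for the split by ATRA, which points to a structure of the samples by ATRA.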
